A study of Mus musculus with 2 samples.

How the data were processed

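Long-read RNA sequencing data of hippocampus from 18 to 20 month old female B6CASTF1/J mice were taken from 1 deposited series with 2 libraries, which the labels call biological replicates 1 and 2. The labels conflict on whether they came from different animals, so values are compared between libraries. They form 1 group, so no contrast between conditions exists. For each library a table of transcript models with read counts and an annotation file with the models' exons were deposited.

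The deposited unit of the quantification columns is counts, raw reads per transcript model, per the file headers and from their whole values with a minimum of 1. The other columns used, in units named as other in the file survey (number of exons, model length in nt, and mm10 start and end positions), are given per the file headers. According to the deposited text, the genome build is mm10 and the annotation GENCODE M21 with spike-ins, and the annotation files name TALON as the source of unannotated models. The aligner, the tool versions and the read filters are not given in the sources used here. TALON places each model in a class: known, incomplete splice match (ISM), new combination of annotated splice sites (NIC), model with an unannotated splice site (NNC), genomic, antisense or intergenic. The ERCC spike-ins were used as a control, and the SIRV spike-ins named in the labels were not analysed here.

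Replicate 1 held 1145830 reads in 157815 models and replicate 2 held 884194 reads in 127311 models, of which 8027 and 14492 reads were spike-ins. Intervals are 95% Wilson intervals, and a count of 0 allows up to 3 reads. Both cover counting error only.

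CPM, counts per 1000000 reads, used the reads assigned to annotated mouse genes as the denominator, without spike-ins, antisense and intergenic models. Values of genes are means ± SD over the libraries, and for lists the medians of each library are given beside the median of the members' mean CPM. Gene levels were correlated as log2(CPM + 1). The test between the libraries was a 2-sided exact binomial test of the reads in replicate 2 out of those in both, against the share given by library sizes scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16. It covered genes with 10 or more reads in both libraries together, with Benjamini-Hochberg adjustment at 0.05. The common dispersion came from edgeR fitted with an intercept only. Log2 ratios of genes used a prior of 0.5 reads. The test treats reads as independent and the libraries as fixed, so a call states a difference between these libraries beyond counting error and not between animals in general. The length trend was a lowess curve with a fraction of 30% on log2 length of the most read annotated isoform, fitted on genes with 50 or more reads, and the test was repeated against the share it gave.

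There were 22 lists with 222 genes, of hippocampal cell types, glia, vessels, membranes, neighbouring tissue and blood, and of functions. The median of the members' mean CPM was ranked among 10000 random lists of the same size from 15021 genes with reads in both libraries. Adjustment was done over all genes tested and over the list alone. Prkcd, Apoe and Clu stand in more than 1 list.

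Isoform shares used reads with a complete splice pattern (known, NIC and NNC). Annotated single-exon isoforms count among the known. Known models were matched between libraries by identifier and others by their intron chain. Fisher's exact test set the main isoform against all others. It was run over the 47 of 76 fixed genes that had at least 50 reads in each library. It was also run over all genes with at least 20 reads in each library and more than 1 isoform. Exon inclusion was the share of reads of models that include an internal exon among these and the reads of models whose intron spans it, for exons with at least 20 informative reads in each library. Exons that no read of either library skipped were left out, except in the check of exons that no annotated transcript skips. A microexon had at most 27 nt, and exons at 10 to 90% inclusion were called partly included. A model recurred when its intron chain was also a model of the other library. Single-exon antisense and intergenic models were matched by a reciprocal overlap of 50%, a rule chosen after the files were seen. Loci needed 5 or more reads in each library. A single-exon model counted as inside exons when 90% of it lay in them. The closest annotated isoform of an unannotated chain was the one with the fewest introns not shared.

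The text names genes by a rule: in each list the 2 to 4 members with the highest mean CPM and those not detected, and the 10 nuclear and 3 mitochondrial genes with the highest CPM. Among genes that differ it takes the 5 largest ratios each way. It also takes the 10 fixed isoform genes with the most reads, the 10 genes with the most reads whose main isoform is unannotated, and the 5 largest changes of isoform share. Of exons it takes the 15 partly included exons of fixed genes and 10 microexons with the most reads. Genes named beyond it, such as list members that passed the test, Syn1, Mapt, further microexons and the loci, were chosen after their values were seen. Some genes that the rule takes are not reported here.

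The tests were tested on simulated data drawn from the observed counts. The simulated libraries differed by counting error and the planted changes alone, without the further spread between the libraries seen in the data. The false calls below therefore give no error rate for the calls made on the data. Of 100 planted 2-fold gene differences 53 were recovered and of 100 4-fold ones 92, with 9 false calls among 11840 genes. A shift of 25 points in isoform share was recovered in 86 of 200 genes with 1 false call, and shifts of 25 and 40 points in exon inclusion in 44 and 144 of 200 exons with 0 false calls.

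The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives were other minimum read counts, a pseudocount of 0.1 CPM, size factors of DESeq2 1.42.0, scaling by total reads, reads of known models alone, a denominator without mitochondrial genes, thinning of the deeper library, a tolerance of 10 nt for splice sites, and each library alone. Later alternatives left out the ribosomal DNA locus, removed the length trend, gave each shared intron chain 1 gene and class, left out genes that overlap others, left out NNC models or unannotated exons, counted single-exon genomic models inside exons as ISM, and left out unannotated single-exon models. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3, were used. Random steps used the seed 1, the permutation test on spike-ins used 100000 permutations, and the shuffle of directions over gene lists 10000.

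Reads themselves and a genome sequence were not used here, so priming at internal adenines, strain variants and alleles were not examined.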

Results

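Long-read RNA sequencing, in which 1 read can cover a cDNA molecule from end to end, was used to profile the hippocampus of aged female B6CASTF1/J mice. This strain is the F1 hybrid of a C57BL/6J and a CAST/EiJ parent. The mice were 18 to 20 months old, and 2 µg of RNA entered each of 2 libraries, labelled as biological replicates 1 and 2. The labels conflict on whether these came from different animals: the sample descriptions of both name the same animal and cDNA and both carry the same donor, while another field of replicate 2 names a different animal and cDNA. The spread is therefore that between libraries, which may or may not include that between animals. The libraries form 1 group, so the measurements below describe the transcripts of this tissue and the spread between the libraries (n = 2), and no condition was compared with another. Tests between the libraries compare those libraries only. Replicate 1 held 1145830 reads and replicate 2 held 884194 reads, and 90.6% and 87.8% of their mouse reads were assigned to annotated genes. Genes with at least 1 read numbered 17013 and 16710, and 15021 genes had reads in both libraries. Levels are given as CPM, the count of a gene per 1000000 reads assigned to annotated mouse genes. The limit that a count of 0 allows, 3 reads, stands for 2.91 CPM in replicate 1 and 3.93 CPM in replicate 2. All intervals are 95% Wilson intervals and cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

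The most abundant genes included Apoe, Ncdn and Ubb. Calm2 stood at 2909 ± 692 CPM (SD, n = 2). Apoe, the lipid carrier made mainly by astrocytes, reached 6142 ± 3089 CPM and Ncdn, a neurite protein, 5009 ± 773 CPM. The polyubiquitin gene Ubb stood at 4151 ± 505 CPM and Cpe, a prohormone-processing carboxypeptidase, 3800 ± 70.1 CPM (SD, n = 2 each). The autophagy gene Gabarapl1 had 3550 ± 2699 CPM, the glycolytic enzyme gene Aldoa 3064 ± 545 CPM, the ferritin heavy chain gene Fth1 3055 ± 1185 CPM and AC149090.1, a gene on the unplaced scaffold JH584304.1, 2995 ± 757 CPM (SD, n = 2 each). Among mitochondrial genes, mt-Co1 had 436 ± 233 CPM, mt-Rnr2 366 ± 331 CPM and mt-Cytb 234 ± 182 CPM (SD, n = 2 each). Cpe did not pass the exact binomial test between the libraries described at the end (adjusted p = 0.606).

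Single-exon reads carried most of the difference for Gabarapl1. It had 1232 such reads inside its exons in replicate 1, classed as incomplete splice matches, and 3786 in replicate 2, classed as genomic, whereas its reads with a complete splice pattern stood at 442 and 497 CPM. For Apoe the complete reads stood at 2721 and 4363 CPM, beside 1275 and 3013 single-exon reads classed as genomic. For AC149090.1 the direction turned, since its complete reads stood at 539 and 378 CPM and all its reads at 2460 and 3531 CPM. Reads of Calm2, Ubb, Fth1, Aldoa and AC149090.1 may be shared with paralogs, pseudogenes or copies on other scaffolds, and their levels are uncertain to that extent.

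Genes of excitatory hippocampal neurons ranked high in the general pyramidal and CA1 lists, lower in the CA3 list and below the middle in the dentate list. A list is given by the median of its members' mean CPM, with the medians of replicates 1 and 2 in parentheses, which can both lie to one side of it. The general list of pyramidal neuron genes had a median of 229 CPM (239 and 219.9), with Nrgn, a postsynaptic protein, at 1655 ± 645 CPM and Slc17a7, the vesicular glutamate transporter, at 1474 ± 95.1 CPM (SD, n = 2 each). This median lay at percentile 99.97 of 10000 random lists of the same size drawn from genes with reads in both libraries. The CA1 list had a median of 108.6 CPM (108.6 and 109.3) at percentile 99.4, led by Wfs1 at 312 ± 132 CPM and Mpped1 at 235 ± 2.53 CPM. The older symbol Nov in this list matched no gene with reads. The CA3 list had a median of 39.4 CPM (42.7 and 41.9) at percentile 77.8, with Nnat at 279 ± 171 CPM and Cpne7 at 211 ± 13.1 CPM. The dentate granule cell list had a median of 20.7 CPM (25.7 and 19.6) at percentile 42.6, with Calb1 at 268 ± 6.61 CPM and C1ql2 at 250.0 ± 40.8 CPM. The granule cell factor Prox1 had 17.3 ± 5.21 CPM (SD, n = 2 each). Interneuron genes had a median of 37.96 CPM (49.5 and 49.7) at percentile 81.2, with the neuropeptide genes Cck at 843 ± 607 CPM, Npy at 108 ± 72.5 CPM and Sst at 83.6 ± 42.8 CPM, and the GABA-synthesis gene Gad1 at 358.3 ± 104.9 CPM (SD, n = 2 each).

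Between the libraries, 1 of 6 tested pyramidal genes differed, as did 2 of 7 in the CA1 list, 2 of 6 in the CA3 list, 1 of 6 in the dentate list and 6 of 10 in the interneuron list. Adjusted over the list alone these counts were 1, 2, 2, 2 and 7. In the interneuron list the 4 genes higher in replicate 2, Cck, Npy, Sst and Pvalb, have main isoforms of 566 to 977 nt, and Gad1 and Cnr1, with 3355 and 5807 nt, were lower. With the trend by transcript length described at the end removed, 0, 1, 1, 0 and 1 of these calls stayed in the same direction (Wfs1, Nnat and Cck), 1 each in the pyramidal and CA3 lists had no isoform length to correct by, and Camk2a, Pou3f1 and Calb1 passed that had not before. On reads of annotated isoforms alone the pyramidal median was 94.4 CPM, the CA3 median 15.8 CPM and the dentate median 16.3 CPM. The order of the CA3 list above the dentate list thus did not hold on those reads.

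Astrocyte genes had the highest median of all lists, 554 CPM (533 and 575), at percentile 100 of the random lists. Beside Apoe it held Aldoc, a glycolytic enzyme of astrocytes, at 1766 ± 152 CPM, the glutamate transporter Slc1a3 at 806 ± 198 CPM and the filament gene Gfap at 719 ± 121 CPM (SD, n = 2 each). Oligodendrocyte genes had a median of 128 CPM (148 and 107), with the myelin genes Mbp at 2238 ± 390 CPM and Cnp at 383 ± 93.4 CPM, and the iron carrier Trf at 662 ± 80.4 CPM. Their precursors had a median of 30.9 CPM (38.3 and 24.2), led by Olig1 at 102 ± 18.6 CPM and Ptprz1 at 66.4 ± 25.4 CPM. Microglial genes had a median of 67.7 CPM (52.4 and 73.3), with the receptor gene Csf1r at 118 ± 9.08 CPM and Tmem119 at 80.4 ± 24.8 CPM. Genes associated with aged or activated glia had a median of 64.3 CPM (54.8 and 71.3), with the cathepsin genes Ctsb at 841 ± 10.2 CPM and Ctsd at 729 ± 20.5 CPM, and Il33 at 107 ± 8.95 CPM (SD, n = 2 each). Itgax had no read in either library, which does not exclude levels up to 2.91 and 3.93 CPM at this depth.

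Of the tested astrocyte genes 6 of 11 differed between the libraries, 3 each way, and of the oligodendrocyte genes 5 of 8, with Mbp, Cnp and Mobp among the 4 lower in replicate 2 and Opalin higher. The counts were 1 of 6 for precursors, 2 of 11 for microglia and 4 of 12 for aged or activated glia. Adjusted over the list alone they were 7, 5, 0, 2 and 6 in the same order. With the length trend removed 2, 2, 0, 0 and 0 of these calls stayed in the same direction (Aldoc, Apoe, Mbp and Cnp). Slc1a2 and Ctsb, higher in replicate 2, and P2ry12, lower, passed that had not before. On reads of annotated isoforms alone the precursor median was 17.1 CPM.

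Choroid plexus, leptomeningeal and neighbouring-tissue lists had medians under 20 CPM, below the vessel list, although single members stood far higher. Among the random lists they lay at percentiles 6.52 (choroid plexus), 17.7 (leptomeninges), 37.4 (neocortex), 24.1 (thalamus and habenula) and 9.77 (striatum), and the vessel list at 71.4. The neocortical list lay near the dentate list (20.7 CPM, percentile 42.6), so these medians do not tell hippocampus from neighbouring tissue. Endothelial and mural genes had a median of 31.4 CPM (26.2 and 36.7), with Bsg at 898 ± 294 CPM and Cldn5, a tight-junction gene, at 175 ± 39.3 CPM. Choroid plexus and ependymal genes had a median of 7.49 CPM (5.82 and 5.24), but Enpp2 stood at 237 ± 96.6 CPM and the choroid plexus transthyretin gene Ttr at 215 ± 33.5 CPM. Leptomeningeal genes had a median of 10.4 CPM (11.6 and 13.1), with Ptgds, a prostaglandin synthase also made by oligodendrocytes, at 1253 ± 1205 CPM and Slc6a13 at 32.4 ± 17.1 CPM. Medians of neighbouring tissue were 17.6 CPM (19.4 and 17.02) for neocortex (Fezf2 38.4 ± 0.582 CPM, Lamp5 37.3 ± 4.70 CPM). They were 13.02 CPM (11.6 and 14.4) for thalamus and habenula (Calb2 61.4 ± 11.3 CPM, Prkcd, which the CA3 list also holds, 39.4 ± 3.57 CPM) and 9.10 CPM (7.76 and 9.16) for striatum (Ppp1r1b 85.9 ± 0.755 CPM, Penk 49.8 ± 12.9 CPM). The habenular gene Pou4f1 had no read in either library. Blood genes had a median of 7.76 CPM in replicate 1 and 54.3 CPM in replicate 2, with Hba-a1 at 207 ± 177 CPM and Hbb-bs at 78.0 ± 69.2 CPM (SD, n = 2 for the genes of this paragraph). The paired globin genes are near copies of each other, so the split between copies is uncertain.

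All 4 tested globin genes were higher in replicate 2, adjusted over the list alone 4 as well, and 2 passed with the length trend removed. In the vessel list 5 of 11 differed (5 adjusted over the list alone), in the choroid list 1 of 6 (1), in the leptomeningeal list 2 of 5 (2), and with the length trend removed 1, 1 and 2 of these calls stayed in the same direction, while Ttr passed that had not before. By the exact binomial test 0 of 7 neocortical, 0 of 4 thalamic and 0 of 5 striatal genes passed, and 0 adjusted over the list alone. At an unadjusted p under 0.05 there was 1 gene in each, Rorb (exact p = 0.0198), Rora (exact p = 0.0129) and Drd1 (exact p = 0.0115), of which Rorb passed with the length trend removed. On reads of annotated isoforms alone the endothelial median was 20.7 CPM and the striatal median 5.04 CPM. The neocortical and thalamic medians were 13.9 and 14.1 CPM on those reads, near the CA3 and dentate medians of 15.8 and 16.3 CPM.

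Synaptic genes had a median of 209.9 CPM (222.1 and 222.5), at percentile 100 of the random lists. The vesicle release genes Snap25, Syp and Vamp2 led with 1903 ± 162, 1370 ± 8.14 and 1364 ± 30.1 CPM, followed by the vesicle-binding synapsin gene Syn2 at 917 ± 220 CPM (SD, n = 2 each). Of 19 synaptic genes, 9 differed between the libraries, 8 of them lower in replicate 2, among them the glutamate receptor genes Gria1, Gria2, Grin1 and Grin2a, and 1 higher, the scaffold gene Dlg4. Adjusted over the list alone 10 passed, and with the length trend removed 8 passed, 7 of them lower. Of these 6 had been called before in the same direction, and Snap25 and Grin2b had not. Genes linked to neurodegeneration had a median of 192 CPM (179 and 204), with the prion protein gene Prnp at 1872 ± 3.54 CPM, App, the amyloid precursor, at 1347 ± 194 CPM and the kinase gene Ptk2b at 1045 ± 297 CPM beside Apoe. Of these genes 8 of 14 differed (8 adjusted over the list alone), and with the length trend removed Apoe stayed and Mapt passed that had not before. Neuronal splicing regulators had a median of 77.4 CPM (83.4 and 74.6), led by Celf4 at 812 ± 85.8 CPM, Khdrbs3 at 437 ± 25.4 CPM and Rbfox3 at 414 ± 76.6 CPM. Of these 5 of 18 differed (5 adjusted over the list alone), and with the length trend removed 3 stayed in the same direction and Nova1 passed that had not before. Long noncoding RNAs had a median of 67.97 CPM (53.3 and 91.6), with the imprinted Meg3 at 391.8 ± 49.4 CPM, Snhg11 at 161 ± 31.5 CPM and Miat at 136 ± 51.01 CPM. Of these 5 of 11 differed (5 adjusted over the list alone), and with the length trend removed Malat1 stayed and Neat1 passed that had not before. Immediate early genes had a median of 53.8 CPM (47.998 and 53.02), with Junb at 231 ± 10.1 CPM, Arc at 170 ± 38.3 CPM and Jun at 102 ± 17.04 CPM. Of these 0 of 10 passed the exact binomial test, 0 adjusted over the list alone and 2, Arc and Dusp1, at an unadjusted p under 0.05. On reads of annotated isoforms alone the median was 22.1 CPM for the noncoding RNAs and 13.9 CPM for the splicing regulators.

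**Figure D1:**
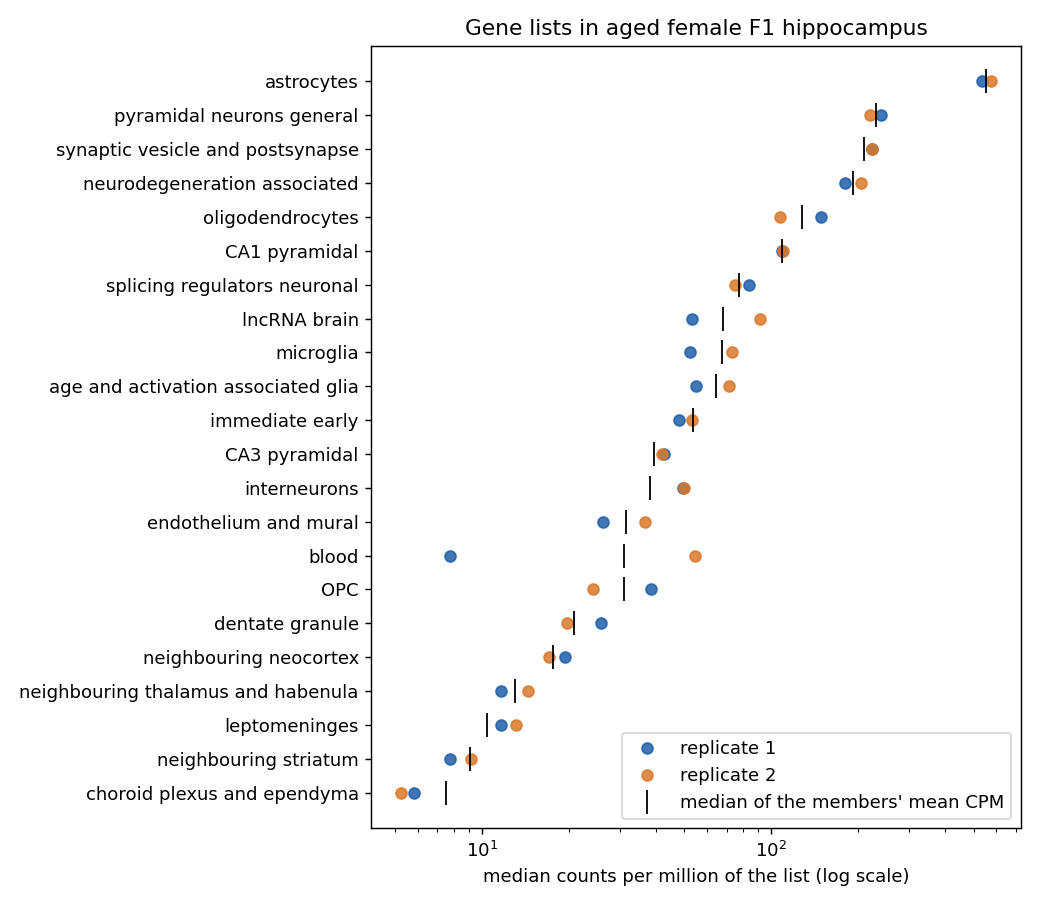
Median CPM of each of 22 gene lists on a log axis, with 1 point for each library and a bar at the median of the members' mean levels. Astrocyte, pyramidal and synaptic genes lie highest at 554, 229 and 209.9 CPM, and the blood list shows the widest gap between the libraries, 7.76 against 54.3 CPM.

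Of the 47 genes fixed for isoform analysis that had at least 50 reads of a complete splice pattern in each library, 32 had a main isoform with over 50% of these reads. When reads of all classes were counted, which also admits other genes of the list to the minimum of 50, the number was 24. Apoe-206 made up 97.5% ± 0.146 of the reads of Apoe that matched a complete splice pattern, Prnp-201 97.5% ± 0.456, Gnas-208 92.3% ± 0.877, Snap25-201 89.0% ± 0.336 and App-201 88.7% ± 0.659 (SD, n = 2 each). App-201 has 16 exons. The 17-exon App-202 held 3.44% ± 0.605 (SD, n = 2). The pyruvate kinase gene Pkm used Pkm-202 at 88.2% ± 0.661 against 9.79% ± 0.742 for Pkm-201, which carries the other of a pair of mutually exclusive exons (SD, n = 2 each). The myelin basic protein gene used the 5-exon Mbp-211 at 68.7% ± 1.40 and the 6-exon Mbp-212 at 15.3% ± 0.292, and the kinase gene Camk2b used Camk2b-209 at 72.9% ± 3.00. Ndrg4 used Ndrg4-202 at 64.3% ± 0.542, and Ndrg2 used Ndrg2-202 at 37.9% ± 0.114 (SD, n = 2 each). Of 76 fixed genes, these were the 47 with enough reads of a complete splice pattern. The main isoform was annotated in 39 of them and unannotated in 8. It held over 80% of the reads in 8, and it was the same in both libraries in 44. Among the rest, the synapsin gene Syn1 divided its reads between Syn1-202 at 52.7% ± 1.05 and Syn1-201 at 44.4% ± 1.26. The tau gene Mapt used Mapt-204 at 60.8% ± 7.06 (SD, n = 2 each).

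None of the 47 main isoform shares differed between the libraries by Fisher's exact test after Benjamini-Hochberg adjustment over the list (smallest adjusted p = 0.681), and 3 did at an unadjusted p under 0.05. With all reads of a gene as the denominator the share was 59.0% for Apoe and 42.8% for Camk2b, and with annotated models alone it was 65.7% for Ndrg2.

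Across genes with enough reads the main isoform was mostly the same in both libraries. Of 5292 genes with at least 20 complete-splice reads in each library, 5029 (95.03%) had the same main isoform in both libraries, at a median share of 84.3%. The shares correlated across genes with Pearson's r = 0.933. Of 5005 genes with at least 2 isoforms 7 passed Fisher's exact test at an adjusted p under 0.05, and 238 had an unadjusted p under 0.05. The reticulon gene Rtn1 used Rtn1-201 at 47.1% of 1426 reads in replicate 1 and 62.0% of 1076 in replicate 2 (exact adjusted p = 2.63e-10). Ss18l2-207 stood at 34.3% of 70 reads and 63.8% of 174 (exact adjusted p = 0.0238), whereas 2900097C17Rik-201 stood at 68.5% and 54.1% (exact adjusted p = 0.000405). Both are annotated single-exon isoforms, which have no splice pattern to match. Single-exon models made up 18.5% of mouse reads in replicate 1 and 27.5% in replicate 2. Podxl2-210, at 84.7% and 70.8%, and Olfm1-201, at 47.5% and 36.3%, also passed and are named after their values were seen. The other calls were Camta2, 74.1% against 0%, and Plppr2-201, 97.8% against 55.8%, and both rested on how a model was assigned. The same intron chain of Camta2 was classed as a new combination with 351 reads in replicate 1 and as an incomplete match with 115 reads in replicate 2. A chain counted for Plppr2 in replicate 2 with 80 reads was counted for Ccdc159 in replicate 1 as an incomplete match. With 1 assignment per chain in both libraries the shares were 74.1% and 69.7% for Camta2 and 97.8% and 94.8% for Plppr2, and 5 genes remained called. The calls were not corrected for transcript length. Across 2450 genes with at least 50 such reads in each library, Spearman's rho was -0.153 between the change in the share of the main isoform from replicate 1 to 2 and its length minus the read-weighted mean length of the other isoforms of the gene, a relation computed after the calls were seen.

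The depth limited this comparison, since in simulated data a shift of 25 percentage points was recovered in 86 of 200 genes. With a minimum of 10 reads 12 genes passed. With all reads of a gene 500 genes passed, but incomplete matches then count as isoforms too. Unannotated single-exon models were grouped by class, and the class of such reads can differ between the libraries, as for Gabarapl1. The 500 genes therefore do not show what more depth would find.

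Receptor, metabolic and myelin genes of the fixed list had exons that only a part of their transcripts included. In Pkm, of 2 mutually exclusive 167-nt exons on chromosome 9 (mm10), the upstream one (59675029 to 59675195) was included in 89.9% ± 0.523 of informative reads and the downstream one (59675568 to 59675734) in 10.02% ± 0.515 (SD, n = 2 each). The AMPA receptor genes Gria1 and Gria2 each have a pair of alternative 115-nt exons, known as flip and flop. In Gria1 on chromosome 11 they were included at 81.2% ± 1.25 (57309769 to 57309883) and 18.3% ± 0.194 (57310608 to 57310722). In Gria2 on chromosome 3 they stood at 72.0% ± 1.14 (80691320 to 80691434) and 28.6% ± 0.407 (80690404 to 80690518). The NMDA receptor gene Grin1 included its 111-nt exon (chromosome 2, 25294438 to 25294548) in 45.8% ± 5.08. In Mbp the 123-nt exon (chromosome 18, 82578936 to 82579058) was included in 18.4% ± 1.34 and the 78-nt exon (82561778 to 82561855) in 11.2% ± 0.0163. Included in most reads were a 39-nt exon of Ndrg4 at 87.5% ± 0.774 and a 45-nt exon of Camk2b at 87.7% ± 1.53. Exons of 168 and 36 nt in the amyloid precursor-like gene Aplp2 stood at 85.3% ± 0.874 and 81.1% ± 1.31. A 42-nt exon of Ndrg2 was included in 33.6% ± 1.47 (SD, n = 2 for all values of this paragraph).

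**Figure D2:**
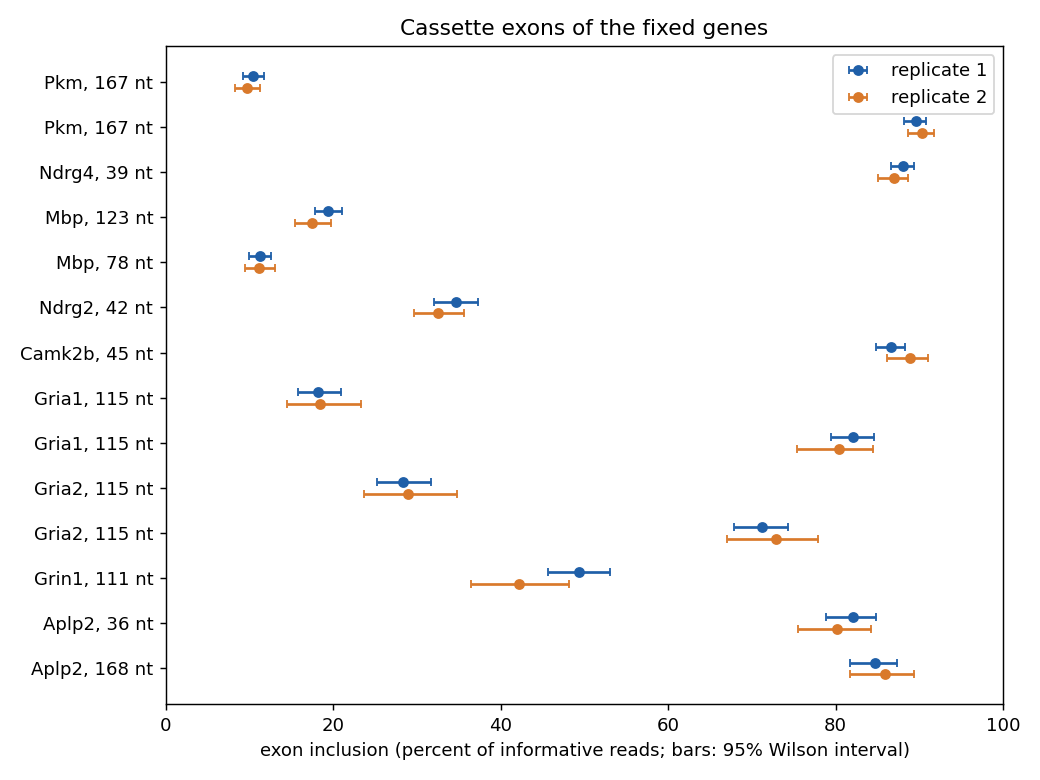
Inclusion of the cassette exons named above in the fixed genes, in percent of informative reads, 1 point per library with its 95% Wilson interval. Values run from 10.02% for the downstream Pkm exon to 89.9% for the upstream one, and Grin1 shows the widest gap, 49.4% and 42.2% (Fisher's exact p = 0.0463, adjusted p = 1).

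Microexons, internal exons of at most 27 nt, were more often partly included than longer exons when models of all classes were counted. On annotated models alone, which left 35 microexons, this was not clear (below). The comparison took the 14786 exons in 3929 genes with at least 20 informative reads in each library that any read skipped. Exons that no read skipped were left out, so the shares are not those of all exons. Among those taken, 64 of 247 microexons (25.9%) and 1318 of 14539 longer exons (9.07%) had an inclusion of 10 to 90%. The odds ratio was 3.51 (Fisher's exact p = 2.05e-14, across exons, which are not independent replicates). Of the exons at 10 to 90% inclusion 58.8% had a length that is a multiple of 3. Among the exons taken that were included in over 90% of reads it was 39.2% (odds ratio 2.22, Fisher's exact p = 3.94e-43). Of the partly included microexons 56 of 64 (87.5%) had such a length. Among them, named after their values were seen, were an 18-nt exon of the actin regulator Nckap1 at 52.2% ± 3.99 (chromosome 2, 80571213 to 80571230), a 24-nt exon of the kinase gene Mink1 at 89.7% ± 0.324 (chromosome 11, 70609408 to 70609431) and a 15-nt exon of the endocytosis gene Snap91 at 86.9% ± 3.90 (chromosome 9, 86798830 to 86798844; SD, n = 2 each). The microexons with the most reads were near complete inclusion in Aplp1 (24 nt, 99.8% ± 0.142), Selenow (25 nt, 99.7% ± 0.3001), Ptk2b (25 nt, 99.5% ± 0.0440), Sirpa (25 nt, 98.4% ± 0.0901), Bsg (25 nt, 94.0% ± 0.501) and Git1 (27 nt, 92.1% ± 0.127). They were near 0 in Nrgn (18 nt, 0.0326% ± 0.0460), in the unannotated 26-nt exon of Ndrg2 (0.0873% ± 0.124), and in an unannotated 19-nt and an annotated 27-nt exon of the motor protein gene Kif5c (0.0455% ± 0.0643 and 0.155% ± 0.220; SD, n = 2 each).

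Inclusion of the partly included exons correlated between the libraries across exons with Pearson's r = 0.954. Of the 14786 exons taken 0 differed between the libraries by Fisher's exact test at an adjusted p under 0.05, while 128 had an unadjusted p under 0.05. In simulated data a shift of 25 points was recovered for 44 of 200 exons and a shift of 40 points for 144 of 200, so a count of 0 leaves room for shifts of 25 points in many exons. The low values of short exons are uncertain, since 21 of 137 annotated exons of at most 27 nt that no annotated transcript skips, the Nrgn exon among them, were read at under 10% inclusion, against 8 of 39409 longer ones (Fisher's exact p = 1.80e-46). The loss lay mostly in the shortest, with 4 of 4 exons of 1 to 10 nt, 12 of 21 of 11 to 20 nt and 5 of 112 (4.46%) of 21 to 27 nt. On annotated models alone 18 of 35 microexons (51.4%) and 413 of 1140 longer exons (36.2%) were partly included. The odds ratio for microexons was then 1.86 (Fisher's exact p = 0.0755). With annotated exons only, in models of all classes, it was 3.84 (Fisher's exact p = 7.64e-15). Without models with an unannotated splice site it was 3.68 (Fisher's exact p = 1.97e-12). These last alternatives were chosen after the result was seen.

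Annotated isoforms carried most of the reads, while most models belonged to other classes. Reads of known isoforms made up 60.7% ± 2.80 of mouse reads. Incomplete splice matches, which lack exons at an end of a known isoform, made up 10.6% ± 0.000391. New combinations of annotated splice sites held 6.69% ± 1.79 and models with an unannotated splice site 3.89% ± 0.512. Genomic models, which do not follow the splicing of their gene, held 7.66% ± 3.24, antisense models 8.98% ± 0.9498 and intergenic models 1.49% ± 0.912 (SD, n = 2 each). Of the models themselves 15.02% ± 1.39 were known, 24.3% ± 1.65 incomplete, 18.1% ± 3.84 new combinations and 16.8% ± 2.49 had an unannotated site (SD, n = 2 each). The class shares differed between the libraries beyond counting error (chi-square 27438, df 6). Known reads made up 62.7% (95% interval 62.6 to 62.7) in replicate 1 and 58.7% (58.6 to 58.8) in replicate 2, and genomic reads stood at 5.37% (5.33 to 5.42) and 9.96% (9.89 to 10.02). The equal totals of incomplete matches hid opposite parts, 8.89% and 7.75% for multi-exon models and 1.73% and 2.86% for single-exon ones. Of the genomic reads 60.6% and 69.4% were single-exon models inside the exons of their own gene, like those of Gabarapl1, so the border between these classes is uncertain. Counted together with the incomplete matches they made up 13.9% and 17.5% of reads. A single locus, the ribosomal DNA repeat on chromosome 17, held 2.97% of mouse reads in replicate 1 and 1.36% in replicate 2, and nearly all of its reads were antisense to Gm26917.

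Unannotated models with 10 or more reads were nearly all found again in the other library. Of all models with new combinations of annotated sites 37.1% ± 12.9 recurred with the same intron chain in the other library, of those with an unannotated site 19.4% ± 6.80, and of incomplete matches 43.1% ± 10.04 (SD, n = 2 each). With 10 or more reads the shares were 99.6% ± 0.552, 99.1% ± 0.492 and 99.6% ± 0.595, and with 1 read they were 22.5% ± 12.3, 12.1% ± 5.81 and 29.1% ± 10.4 (SD, n = 2 each). The share was higher for models of the shallower replicate 2, searched for in the deeper replicate 1, at 31.2% against 13.8% for new combinations with 1 read. Models with 1 read made up 62.0% and 60.9% of all models. When splice sites within 10 nt were counted as equal, 41.4% of models with an unannotated site recurred.

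**Figure D3:**
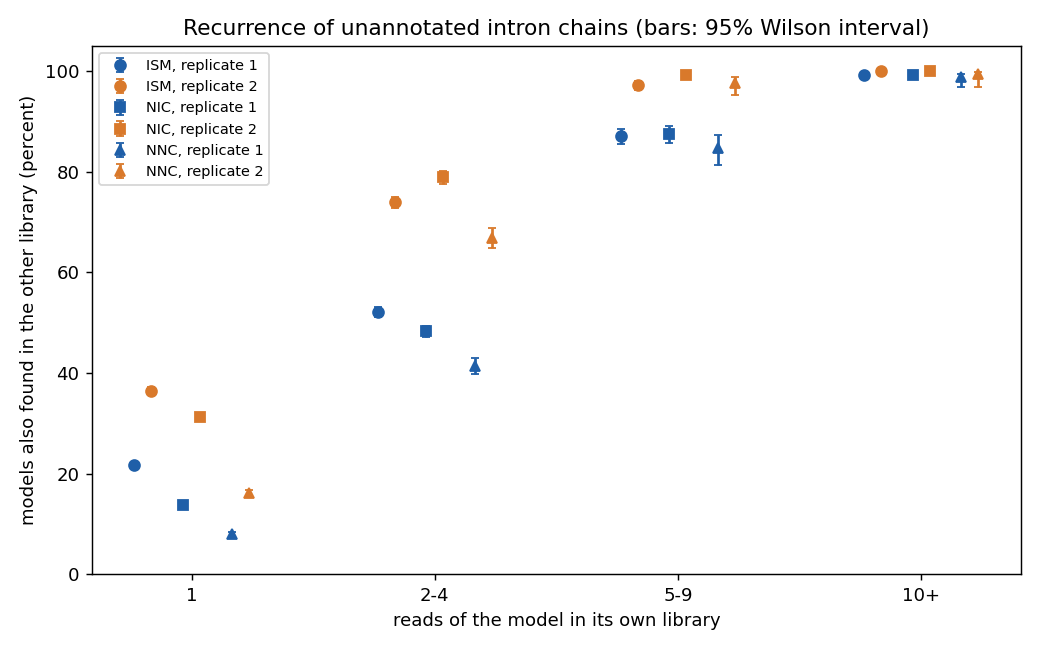
Share of multi-exon models of a library whose intron chain was also found in the other library, in percent with 95% Wilson intervals, by the number of reads of the model, for incomplete splice matches (ISM), new combinations of annotated sites (NIC) and models with an unannotated site (NNC). The shares climb from 7.97% to 36.5% at 1 read to 98.7% or more at 10 or more reads.

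In 248 of 5292 genes (4.69%, 95% interval 4.15 to 5.29) the same unannotated intron chain was the main isoform in both libraries, and in 128 it held over 50% of the reads. Nrgn gave 97.7% ± 0.0922 of its reads to a 3-exon chain on chromosome 9 (37544492 to 37552904) without the annotated 18-nt exon as a separate exon. The flanks changed by 17 nt, so the bases of that exon may be in the reads but placed at a neighbouring exon, which was not tested. The polyamine regulators Oaz1 and Oaz2 gave 96.6% ± 0.123 and 93.0% ± 0.531 to chains that close a 4-nt gap in the annotated isoform. In Pitpna (97.9% ± 1.16), Sept7 (89.1% ± 1.11) and Trim44 (90.9% ± 2.58) the chain lacked annotated exons of 8, 5 and 20 nt. Aplp2 gave 69.0% ± 1.33 to a chain that adds the 36-nt exon to Aplp2-201, and Ctbp1, a corepressor gene, 60.1% ± 1.43 to a chain with a splice site shifted by 3 nt. Apbb1 (69.6% ± 2.89) and Cpne6 (48.6% ± 2.37) used chains with upstream introns absent from the closest annotated isoform. In Apbb1 this was an intron of 6718 nt on chromosome 7 (105574417 to 105581134) and in Cpne6 one of 1271 nt on chromosome 14 (55510710 to 55511980; SD, n = 2 for each share of this paragraph). Compared with the closest annotated isoform, 66 of the 248 chains added introns, 53 moved a splice site by over 10 nt and 30 by at most 10 nt, 22 added an exon, 20 lacked a microexon and 14 another exon.

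For 36 chains no single difference was found, and the kind depends on which annotated isoform is closest. With a minimum of 50 reads in each library the count was 124 genes. Chains that lack an annotated exon of at most 27 nt, those of Nrgn and Trim44 included, are subject to the limit on short exons given above.

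Outside the sense strand of annotated genes 1016 models had at least 5 reads in both libraries, 845 antisense and 171 intergenic. Of the antisense models 834 had a single exon, and single-exon models held 98.4% and 98.6% of antisense reads. Among single-exon antisense models with at least 5 reads, 18.3% and 25.4% of models, with 70.9% and 66.8% of the reads, lay within exons of the gene on the other strand. Without the ribosomal DNA locus these held 45.2% and 58.6% of the reads. The leading models lay opposite Gm26917 on chromosome 17 (39843013 to 39846245, 33653 and 11542 reads) and opposite the synaptic gene Cplx2 on chromosome 13 (54379553 to 54379932, 1460 and 5332 reads). Others lay opposite Snhg11 on chromosome 2 (158382148 to 158384917, 1266 and 788 reads) and opposite Adam22 on chromosome 5 (8072352 to 8078686, 473 and 1113 reads). The leading intergenic model lay on chromosome 15 (103619060 to 103619240, 231 and 1114 reads), 30552 nt from Gm49272. It was 181 nt long, and intergenic models of 173 to 181 nt also led near Rpl27-ps1 and Anp32e. Spike-in RNA, which has no second strand, gave 0.897% (95% interval 0.713 to 1.13) and 0.752% (0.624 to 0.906) of its reads on the opposite strand. With a minimum of 2 reads 3064 models were counted, and with a minimum of 10 reads 445.

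Gene levels followed each other between the libraries, with a graded difference by transcript length. Across genes log2(CPM + 1) correlated with Pearson's r = 0.921 and Spearman's rho = 0.920 (genes are not independent replicates), and edgeR's common dispersion gave a coefficient of variation between the libraries, beyond counting error, of 31.1%. By the exact binomial test with scaled depth, 2562 of 11793 genes (21.7%) differed at an adjusted p under 0.05, 1379 higher and 1183 lower in replicate 2. The majority direction turned with the scaling, from 53.8% higher to 45.4% higher of 2670 genes under total-read scaling. Genes with short transcripts were higher in replicate 2 and genes with long ones lower. The median log2 ratio of replicate 2 over replicate 1 was 1.48 for 197 genes of at most 500 nt, 0.61 for 1041 genes of 1001 to 1500 nt, -0.01 for 2529 genes of 2001 to 3000 nt and -0.55 for 1070 genes above 6000 nt. Spearman's rho between the ratio and the length of the most read annotated isoform was -0.566 across 11080 genes. Over 20 spike-ins of 505 to 1136 nt, rho was -0.829 (permutation p = 2.0e-05, the smallest that 100000 permutations can give, 2-sided). The log2 ratio changed by -0.913 (standard error 0.161) per doubling of spike-in length. For 850 genes with 20 or more reads in that range the change was -0.438 (standard error 0.0781). With the length trend removed 926 genes passed, 565 higher and 361 lower, and 593 of them were among the 2562, 580 in the same direction. The rest passed only with the correction. Spearman's rho between the corrected ratio and length was 0.0933, so a weak relation of the opposite sign remained. Of the 2562 genes 2427 had a length to correct by. The correction itself is large for very short transcripts, and took the 53-nt Gm22123 from a log2 ratio of -1.82 to -5.36.

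The genes with the largest ratios rested on models that are hard to place. Cfap77, a cilium gene, had 40 reads in replicate 1 and 0 in replicate 2. In the same order Tmc4 had 72 and 0, AC129217.1 28 and 0, Slc24a5 16 and 0 and Gm15591 13 and 0. In the other direction the protocadherin gene Pcdhga2 had 1 and 77 reads, Gm29253 0 and 25, Gm42477 0 and 24, Gm26723 0 and 22 and Gm28778 0 and 18. In 8 of these 10 genes the leading model was a single-exon model classed as genomic. Tmc4 had 71 and 22 reads once each intron chain had 1 assignment in both libraries. Tmc4, AC129217.1, Gm28778, Gm29253 and Pcdhga2 overlap other genes on the same strand, Pcdhga2 with Pcdhgc5 (258 and 106 reads). With the length trend removed, the largest ratios included the transcription factor gene Egr2, with 2 and 27 reads. Its leading model held 25 reads in replicate 2 and was again a single exon classed as genomic. That model ran from 67542188 to 67547498 on chromosome 10, beginning at the annotated end of Egr2. Of its length 56.3% lay in exons of Ado on the other strand, so whether these reads belong to Egr2 is uncertain. Hnrnpul2 had 2 and 25 reads and overlaps AC129217.1. The leading models of both genes were single exons that began at the same base of chromosome 19 (8831455). That of AC129217.1 was classed as genomic in replicate 1 and that of Hnrnpul2 as an incomplete match in replicate 2. The opposite ratios of these genes may therefore rest on how reads of 1 locus were assigned.

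**Figure D4:**
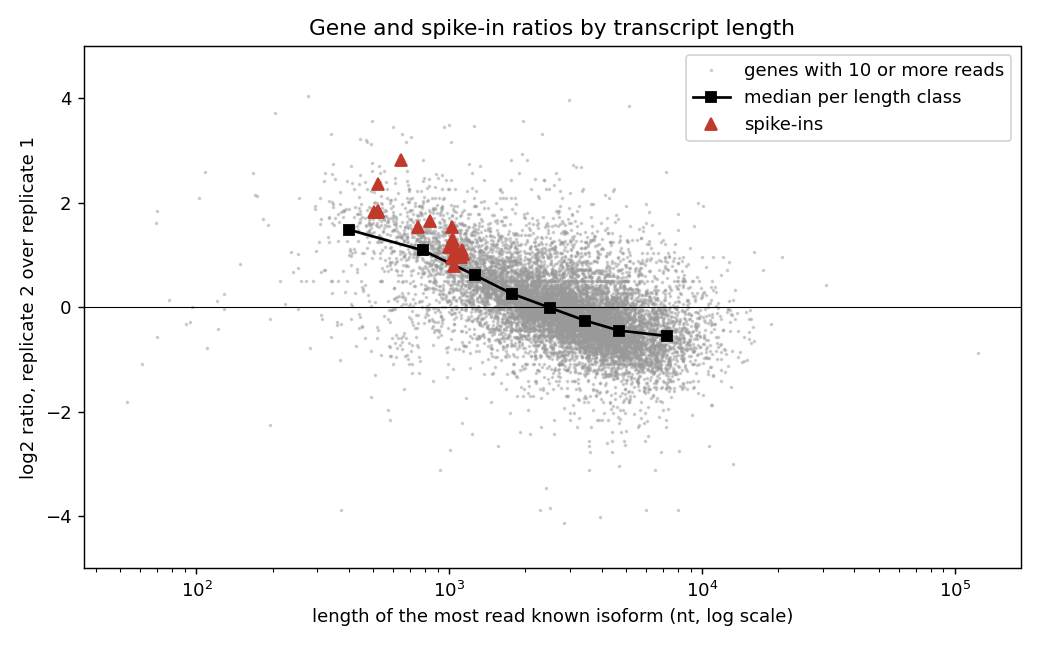
Log2 ratio of replicate 2 over replicate 1 for each gene with at least 10 reads (grey), the median per length class (black squares) and 20 spike-ins (red triangles), against the length of the most read annotated isoform on a log axis. Medians fall from 1.48 at the shortest class to -0.55 at the longest, the spike-ins fall with length over 505 to 1136 nt, and genes with ratios beyond 5 on either side lie outside the axis.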

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

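The tests on spike-in length, on short exons lost in the alignment and on the differences left after the length trend were chosen only after the result was seen, as were the count of genomic reads inside exons, the comparison of list directions with the length trend, and those directions with the trend removed. The libraries form 1 group, so no biological explanation was tested, and age, sex and strain are the same in both.

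Reads on the strand opposite to the spike-ins, a signal in data outside the main measurement, numbered 72 in replicate 1 and 109 in replicate 2. Reads on chromosome Y in female tissue, above the limit that a count of 0 allows, numbered 32 in replicate 1 and 31 in replicate 2. Of these 29 and 30 came from single-exon models and 23 and 19 from intergenic ones. The Y genes Ddx3y, Eif2s3y and Kdm5d had 0 reads in both libraries, Uty had 0 and 1, and Xist had 55 and 32.

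Incomplete splice matches made up 10.6% of reads in both libraries. Truncation of long molecules is consistent with Spearman's rho across genes between the incomplete share and main isoform length, 0.326 and 0.316, and with 7.01 and 7.30 models lacking 5' exons for each model lacking 3' exons. A difference between preparations of over 5 percentage points, the bound set in advance, is argued against by a difference of 0.000552 points. Smaller differences are not excluded by that bound, since multi-exon models were 1.14 points lower and single-exon ones 1.14 points higher in replicate 2, and the difference was 3.66 points with genomic models inside exons. Their cause was not tested.

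Models with an unannotated splice site held 3.89% of reads. Loss of short annotated exons in the alignment may account for a part of them, since 15.3% of exons of at most 27 nt that no annotated transcript skips were read at under 10% inclusion (16 of 25 exons of at most 20 nt but 5 of 112 of 21 to 27 nt), and reads of models spanning these were 6.72% of the class. Misplaced junctions stay open, since 27.7% of unannotated sites lay within 10 nt of an annotated one, between the bounds set in advance, against 1.17% and 1.23% after a shift of 100 nt. Depth stays open too, since the library shares differed by 0.376 points after thinning but by 0.474 points already before, so that the bound of 1 point decided nothing.

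Gene levels differed between the libraries for 2562 genes. Transcript length goes with rho = -0.566 across genes, and an origin in library preparation or sequencing with rho = -0.829 across spike-ins. The spike-ins were added as a mix and cover only 505 to 1136 nt. In that range their slope was steeper than that of genes, -0.913 against -0.438 per doubling of length. The trends thus match in direction and not in size. Different tissue content of the dissection stays open: 0 of 8 lists with 5 or more called members had 9 of 10 moving one way, but that bound, set in advance, was wrong, since 37 of 46 of those members, each gene counted once and those without an isoform length left out, moved the way the length trend predicts. With the trend removed only 1 list kept 5 or more calls, too few to decide, and 7 of 10 lists with 2 or more calls moved one way against a mean of 4.14 with shuffled directions (permutation p = 0.0497), a count that rests mostly on lists of 2 calls and decides nothing. With the trend removed, 580 of the 2427 called genes with a length stayed past the threshold in the same direction. This does not decide whether length was the whole cause. The test allows no spread around the trend beyond counting error, and the trend uses the length of 1 annotated isoform per gene rather than that of the reads. What lies behind those calls stays open.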

How the results depend on the processing

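Chosen only after the result was seen were the alternatives without the ribosomal DNA locus (classes and antisense reads inside exons), with 1 gene and class per intron chain, with genomic models counted as incomplete matches, with the length trend removed, without overlapping genes, without unannotated single-exon models, without models with an unannotated site (exons), and with annotated exons only. Except where an alternative's own construction shows it, the cause was not tested. No paired analysis was possible because the libraries form a single group. With models of 2 or more and of 5 or more reads, which leaves out models with few reads, known reads were 65.9% and 70.8%, incomplete matches 9.20% and 7.42% and models with an unannotated site 2.04% and 1.40%. With 5 or more, new combinations were 4.25% and antisense reads 7.99%. Incomplete matches were 10.6% after thinning, 10.6% with 1 class per chain, 10.8% without the ribosomal DNA locus and 15.7% with genomic models inside exons, and antisense reads were 6.97% without that locus. With the length trend removed 926 genes differed, and Pearson's r was 0.802 with a pseudocount of 0.1 CPM. On known models alone the list medians in CPM were 94.4 (pyramidal), 81.7 (CA1), 15.8 (CA3), 16.3 (dentate), 51.5 (interneurons), 606 (astrocytes), 158 (oligodendrocytes), 17.1 (their precursors), 93.7 (microglia), 20.7 (vessels), 12.04 (leptomeninges), 13.9 (neocortex), 5.04 (striatum), 63.1 (immediate early), 188 (synaptic), 22.1 (noncoding), 13.9 (splicing) and 143 (neurodegeneration). The synaptic median was 210.3 without mitochondrial genes in the denominator. From each library alone the medians were 108.6 to 109.3 (CA1), 41.9 to 42.7 (CA3), 19.6 to 25.7 (dentate), 49.5 to 49.7 (interneurons), 52.4 to 73.3 (microglia), 5.24 to 5.82 (choroid plexus), 11.6 to 13.1 (leptomeninges), 17.02 to 19.4 (neocortex), 7.76 to 9.16 (striatum), 48.0 to 53.0 (immediate early) and 222.1 to 222.5 (synaptic). Isoform usage differed in 12 genes with 10 or more reads and in 500 with all reads, a count that can rest on how single-exon reads were classed. Partly included exons numbered 2327 with 10 or more and 522 with 50 or more informative reads and 431 on known models, where the odds ratio was 1.86 (exact p = 0.0755). Recurrence of models with an unannotated site was 41.4% with sites within 10 nt, and 99.7% at 10 or more reads after thinning. With 50 or more reads 124 genes had an unannotated main isoform. Loci numbered 3064 with 2 or more reads and 445 with 10 or more. Of all values recomputed 164 counted as unchanged, 80 moved and 1 lost its call. Unchanged meant within the spread or on the same side of the threshold, and for counts within a fixed fold of the main count. By that rule 1720 genes at an adjusted p under 0.01 counted as unchanged from 2562. For class and isoform shares, leaving out 1 library could not count as a move, since each of 2 values lies within 1 SD of their mean. Those rows add nothing to the 164. Depth limits the isoform and exon comparisons, where shifts of 25 points were recovered in 43% of genes and 22% of exons.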

Other observations

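The values on assignment of shared chains and on overlapping genes were computed only after the results were seen, and no hypothesis was tested here.

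Partly included microexons not named above, chosen after their values were seen, included a 27-nt exon of the phosphatase gene Ptpra at 58.5% ± 4.33. A 21-nt exon of the dynactin gene Dctn1 was included at 84.6% ± 3.04 and a 24-nt exon of the membrane-curvature gene Bin1 at 82.2% ± 1.49 (SD, n = 2 each). Among fixed genes with several isoforms, the postsynaptic scaffold gene Homer1 gave 59.2% ± 0.670 of its reads to the 10-exon Homer1-203 and 32.8% ± 0.760 to the 5-exon Homer1-204 (SD, n = 2 each). In the myelin gene Mobp the main isoform, Mobp-204 at 73.7% ± 6.27 (SD, n = 2), carries the annotation of a nonsense-mediated decay transcript.

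Of 43077 intron chains found in both libraries, 2024 (4.70%) had a different class in each and 169 a different gene. Of 644 tested genes that overlap another gene on the same strand 158 differed between the libraries, and without overlapping genes 2399 differed. Spike-ins made up 0.701% of reads in replicate 1 and 1.64% in replicate 2, mitochondrial genes 0.0976% and 0.324% of reads of annotated genes, and single-exon models 18.5% and 27.5% of reads. The median length of the model of a read was 2848 and 2063 nt.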
